A study of Mus musculus with 21 samples.

How the data were processed

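Retinas were dissociated with papain, ganglion cells were sorted by flow cytometry, and SMART-Seq libraries were made from the sorted cells, per the labels' protocols. The gate of the sort is not given in the sources used here. STAR, Picard, HTSeq and edgeR and the build mm10 are named without versions, per the submitters' processing notes, and the annotation and the counting settings, strand included, are not given in the sources used here.

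The authors deposited a table of raw read counts per gene for 21 libraries and 17164 genes, which holds whole numbers. A second deposited table gives log fold changes, taken here as log2, with p-values and FDR values for 17100 genes in each knockout, and its model, covariates and filters are not given in the sources used here. The authors' sample sheet gives sex, batch, the number of aligned reads as counts, the fraction of duplicate pairs (48.0% to 57.6% as percent) and the score of each library on components of sequencing quality. A further 38 columns of per-sample values in that sheet were not used, since part of their headers appear shifted. The deposited gene annotation holds no entry for 2317 of the counted genes.

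Groups follow the sample titles. 1 library has a control title and a CHOP knockout genotype and was left out of all groups. Nothing in the labels says whether libraries of a group come from separate animals, so p-values measure the spread between these libraries, which may be technical. Pairs of libraries within a group differed by more than counting noise, with chi-square values per gene from 12.9 to 64.6 over genes with at least 20 reads in the pair, and no library was a copy of another. ATF4 replicate 1 is female in the sheet, but Ddx3y of the Y chromosome was at 61.4 CPM and Xist at 0.26 CPM in it. Sex was not fitted, since it follows the groups.

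Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr (minimum count 10), which kept 16797 and removed 367, and libraries were scaled by TMM. All 20 libraries of the 5 groups entered a single quasi-likelihood fit (glmQLFit, robust, 15 residual degrees of freedom, biological coefficient of variation 0.407), each comparison was a contrast tested with glmQLFTest, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. Every adjusted p of a gene comes from this edgeR test. CPM are counts scaled to library size with the TMM factors (cpm in edgeR), and log2 CPM use a prior count of 2. Fold changes of genes at 0 in a group are given as bounds against 3 reads summed over that group, and these floors cover counting error only, since reads without molecular identifiers are not independent molecules. Coordinates come from the GENCODE annotation of the same build.

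Before the data were examined, 28 gene lists with 476 named genes were fixed, and the groups, the tests, most alternatives and the rule for named genes were set. The lists cover the integrated stress response, amino acid supply, tRNA synthetases, endoplasmic reticulum chaperones, apoptosis, regeneration, neuropeptides, immunity, ganglion cell identity and subtype, synapses, immediate early genes, cholesterol, respiration, glycolysis, antioxidants, ribosomal proteins and markers of other cell types. Of the named genes 463 matched, and 26 lists with at least 5 measured members were tested with camera (limma 3.58.1, preset correlation 0.01) and Benjamini-Hochberg adjustment over the lists. Adjusted p-values of lists come from camera, with an estimated correlation as an alternative. With the preset correlation 10, 9, 10 and 10 lists passed for ATF3, ATF4, CEBPG and CHOP against control, and with an estimated correlation 0, 0, 0 and 3. Lists of T and NK lymphocyte genes and of monocyte and neutrophil genes were added after immune genes were seen among the largest rises. The lymphocyte list includes Cd96 and Icos, which were among the rises seen, so its test is not independent of what led to it.

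Named genes are the targeted genes, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM and every knockout library on the same side of the control mean, and up to 4 called members per direction of each list by adjusted p. Between knockouts, 5 genes per direction were named by the same rule, and for the overlap the 10 per direction called the same way in most knockouts. Markers of other cells are named by abundance, up to 4 per list. Some genes that these rules name were withheld for evaluation and are left out.

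The edgeR step was tested on simulated counts with 200 genes changed per knockout among 16797, 100 by each of the sizes that follow. At a log2 change of 1 it recovered 64% for ATF3, 47% for ATF4, 51% for CEBPG and 67% for CHOP against control, and at a log2 change of 2 it recovered 91%, 85%, 91% and 95%. False calls were 5.14%, 3.65%, 4.70% and 3.57% of the calls in that order. Of 25 simulated lists, both shifted lists and none of the others were called. The simulated genes varied independently of each other, so this does not test list calls where genes are correlated. The simulation also held far fewer changed genes than were called in the data and no batch difference, so its rates need not carry over.

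The alternatives were DESeq2 size factors and upper-quartile factors, no filter and a stricter filter, fits of only the groups compared, DESeq2 1.42.0, limma-voom with quality weights, a surrogate variable (sva 3.50.0), components of cell markers and of sequencing quality as covariates, a replicate block, the unassigned library as a control, a minimum fold change, camera with an estimated correlation, fry and each replicate left out. Added after the data were seen were fits without X and Y genes, without rod and cone genes, at equal depth, against the other knockouts of the batch, without CEBPG replicates 6 and 8 and with the stress response list without the targeted genes.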

Results

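Gene expression was measured by RNA sequencing in cells sorted as retinal ganglion cells, the neurons whose axons form the optic nerve. They came from C57BL/6 mice 3 days after the nerve was crushed. The cells had received a control guide RNA or guide RNAs against ATF3, ATF4, CEBPG (C/EBP gamma) or CHOP (encoded by Ddit3), which are 4 bZIP transcription factors of cellular stress responses. The groups held 4 control, 5 ATF3 knockout, 2 ATF4 knockout, 4 CEBPG knockout and 5 CHOP knockout libraries, and 1 further library with contradictory labels entered no group. Counted reads per library ran from 6401446 to 11752828 in the controls and from 25267560 to 32776378 in the ATF3 knockouts. They ran from 11929692 to 12404601 in the ATF4, from 9000250 to 29810987 in the CEBPG and from 14272784 to 31543917 in the CHOP knockouts. All 4 controls came from male mice and batch 2 in the submitters' sample sheet, all ATF3, CEBPG and CHOP knockouts from female mice and batch 3, and the ATF4 knockouts from batch 1. No batch held controls together with a knockout, so knockout, batch and, outside ATF4, sex cannot be told apart in the comparisons against control. Only the ATF3, CEBPG and CHOP knockouts shared a batch and a sex.

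The largest component of the expression values, with 24.2% of the variance, set the 4 controls and 2 ATF4 knockouts apart from the 14 libraries of batch 3. The next component, with 13.5%, set the controls and CEBPG knockouts apart from the other knockouts. Within the CEBPG group, replicates 6 and 8 stood far apart from the other libraries on the fourth component (-99.33 and 102.1).

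**Figure D1:**
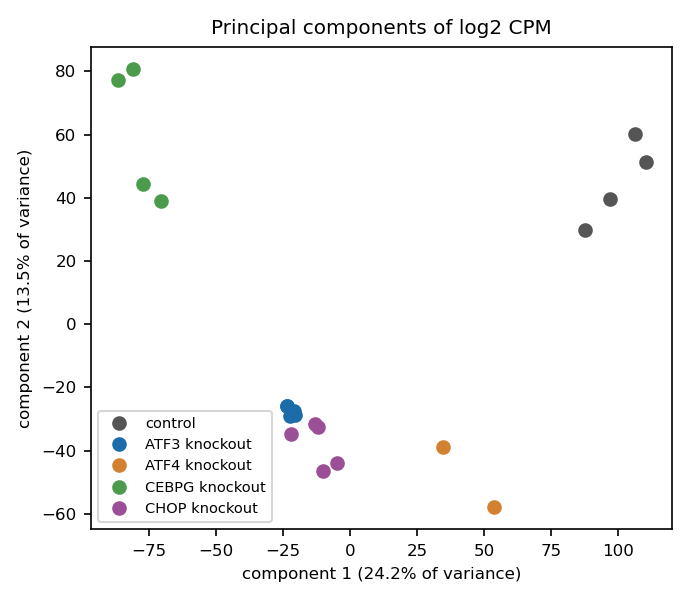
Each point is 1 of the 20 libraries in groups, placed by its scores on the components with 24.2% (horizontal axis) and 13.5% (vertical axis) of the variance of log2 CPM. Controls score from 87.7 to 110.3 on the horizontal axis and CEBPG knockouts from -86.81 to -70.62.

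The transcripts of the targeted genes were compared first, in every library. Atf3 (mm10 chromosome 1, 191170296 to 191218039, minus strand) was at 113 ± 9.28 CPM (SD, n = 4) in the controls and 38.3 ± 6.68 CPM (n = 5) in the ATF3 knockouts (log2 fold change -1.56, SE 0.25, adjusted p = 2.41e-05). No ATF3 knockout library reached the lowest control. It was as low in the CHOP knockouts (-1.62, SE 0.25, adjusted p = 1.48e-05). The difference did not pass in the ATF4 knockouts (-0.25, SE 0.32, adjusted p = 0.603, and -0.54 and -0.01 without ATF4 replicates 1 and 3) or the CEBPG knockouts (-0.61, SE 0.26, adjusted p = 0.0751), where it passed without CEBPG replicate 8 (-0.95, adjusted p = 0.00484). Atf4 (chromosome 15, 80255184 to 80257541, plus strand) fell in the ATF4 knockouts (-0.97, SE 0.18, adjusted p = 0.000211, n = 2). It also fell in the ATF3 (-1.77, SE 0.13), CEBPG (-1.22, SE 0.14) and CHOP (-1.50, SE 0.13) knockouts. Cebpg (chromosome 7, 35046422 to 35056573, minus strand) was at 74.6 ± 21.2 CPM in the CEBPG knockouts (n = 4) and 83.3 ± 7.81 CPM in the controls, a difference that did not pass the test (-0.16, SE 0.16, adjusted p = 0.491). With a single CEBPG library left out that value lay between -0.28, without replicate 9, and -0.04, without replicate 8. Cebpg was lower in the ATF3 (-0.42, SE 0.15, adjusted p = 0.0386), ATF4 (-0.63, SE 0.21, adjusted p = 0.0223) and CHOP (-0.58, SE 0.15, adjusted p = 0.00529) knockouts. The ATF3 call was lost without ATF3 replicate 5, 6 or 7 or control replicate 7 or 8 (adjusted p = 0.0678, 0.0703, 0.0902, 0.0588 and 0.097), and the ATF4 call without ATF4 replicate 3 (adjusted p = 0.229). Ddit3 (chromosome 10, 127290774 to 127296288, plus strand) fell in the CHOP knockouts (-0.43, SE 0.12, adjusted p = 0.00908) and in the ATF3 knockouts (-0.51, SE 0.12, adjusted p = 0.00228). It fell in the CEBPG knockouts too (-0.41, SE 0.13, adjusted p = 0.0186), a call lost without CEBPG replicate 9 or control replicate 7 (adjusted p = 0.0622 and 0.0874). In the ATF4 knockouts it was higher without passing (0.37, SE 0.16, adjusted p = 0.0777), and passed without control replicate 7 (0.48, adjusted p = 0.0186). A second annotated entry named Ddit3 (127290829 to 127293753, plus strand) overlaps the first, and how reads on both were counted is not given in the sources used here. A small edit need not lower the transcript and a count over the whole gene does not read it, so these values do not check the labels. In the authors' deposited table, Atf3 was at -2.34 in the ATF3 knockouts (FDR 0.00421), Atf4 at -1.41 in the ATF4 knockouts (FDR 0.0201) and Cebpg at -0.26 in the CEBPG knockouts (FDR 0.43). Ddit3 in the authors' deposited table was at 0.31, -0.17, 0.09 and 0.33 in the ATF3, ATF4, CEBPG and CHOP knockouts (FDR 0.468, 0.783, 0.715 and 0.535), opposite in sign to the values here in all 4. The log base and the model of that table are not given in the sources used here.

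**Figure D2:**
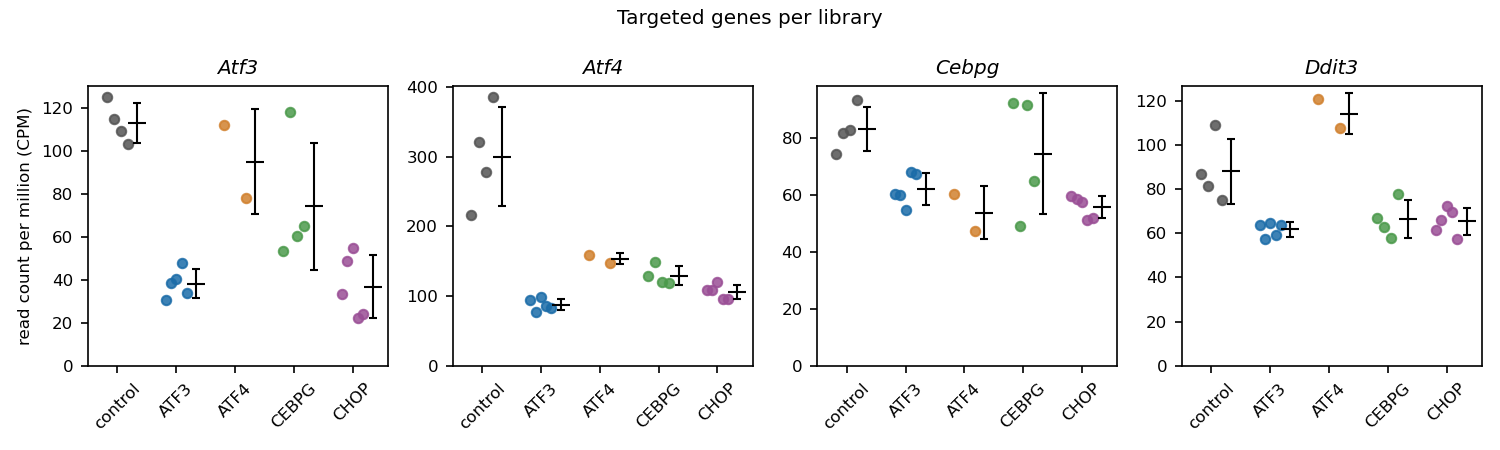
Points are CPM of Atf3, Atf4, Cebpg and Ddit3 in each library, and the bars beside them show the group mean ± SD (control n = 4, ATF3 n = 5, ATF4 n = 2, CEBPG n = 4, CHOP n = 5). Atf4 was below every control in all 16 knockout libraries, and Cebpg in the CEBPG knockouts ran from 49.2 to 92.4 CPM against 74.6 to 93.6 CPM in the controls.

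Ganglion cell identity genes took 0.0865% ± 0.00993 of the counted reads in the controls, where Müller glia genes took 0.774% ± 0.167. Their share was 0.0925% ± 0.00132 in the ATF3, 0.0895% ± 0.00116 in the ATF4, 0.0655% ± 0.00603 in the CEBPG and 0.0828% ± 0.00760 in the CHOP knockouts. Such shares do not measure cell numbers, but reads of other cells enter every comparison. Markers of other retinal cells moved with the groups. Rod photoreceptor genes took 4.91% ± 1.05 of the counted reads in the controls (SD, n = 4), against 0.452% ± 0.0119 in the ATF3 knockouts (n = 5), 0.456% ± 0.0713 in the ATF4 knockouts (n = 2), 0.460% ± 0.114 in the CEBPG knockouts (n = 4) and 0.794% ± 0.157 in the CHOP knockouts (n = 5). All 14 measured rod genes fell in each knockout. The rod list passed the test in every knockout, with adjusted p = 6.84e-23, 2.71e-20, 1.32e-19 and 3.51e-18 in that order, and with an estimated correlation its adjusted p = 0.0595, 0.178, 0.0994 and 0.0503. Amacrine cell genes rose, 11 of 12 in the ATF3 and CHOP knockouts and 10 in the ATF4 and CEBPG knockouts, with list medians of 1.43, 1.56, 0.81 and 1.82 for ATF3, ATF4, CEBPG and CHOP. Slc6a9, a glycine transporter, rose by 1.52 in the ATF3, 1.81 in the ATF4, 0.63 in the CEBPG and 1.98 in the CHOP knockouts. The amacrine list had adjusted p = 3.35e-07, 7.72e-06, 0.000387 and 8.82e-09, and with an estimated correlation adjusted p = 0.0713, 0.247, 0.299 and 0.0429. Of 10 cone genes, 9 fell in the ATF3, CEBPG and CHOP knockouts alike, and the list passed in each (adjusted p = 3.7e-05, 6.11e-07 and 2.34e-06, and adjusted p = 0.092, 0.0994 and 0.0503 with an estimated correlation). Of 12 bipolar cell genes, 11 fell in the CEBPG knockouts (adjusted p = 6.16e-07, and adjusted p = 0.152 with an estimated correlation) and 10 in the CHOP knockouts (adjusted p = 4.57e-05, and adjusted p = 0.182 with an estimated correlation). Microglia genes rose in the CEBPG knockouts, 9 of 15 with none lower (adjusted p = 0.000956, and adjusted p = 0.393 with an estimated correlation), and took 1.15% ± 0.0569 of the reads there against 0.742% ± 0.155 in the controls. Genes of T and NK lymphocytes, a list written after immune genes were seen among the largest rises, took 0.00305% ± 0.000901 of the reads in the controls, 0.0607% ± 0.00316 in the ATF3, 0.0101% ± 0.00577 in the ATF4, 0.358% ± 0.0556 in the CEBPG and 0.0680% ± 0.0123 in the CHOP knockouts.

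**Figure D3:**
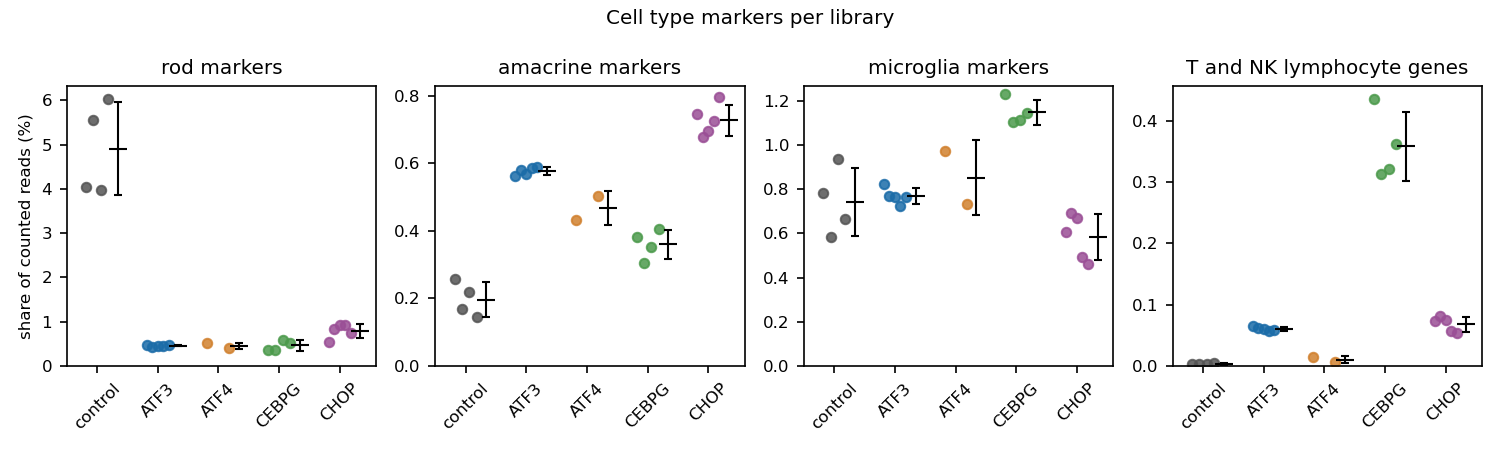
Points are the percent of counted reads on rod, amacrine, microglia and T or NK lymphocyte genes in each library, with the group mean ± SD beside them (control n = 4, ATF3 n = 5, ATF4 n = 2, CEBPG n = 4, CHOP n = 5). Rod markers lie between 3.99% and 6.04% in the controls and below 1% in all 16 knockout libraries.

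The 5 ATF3 knockout libraries were compared with the 4 controls, from which they differ in batch and sex as well as in the knockout. Regulators of the integrated stress response, the program that ATF4 carries out when protein synthesis is curbed, were lower: 9 of 17 fell, 2 rose and 6 did not pass, with the same counts adjusted over the list alone and a median of -0.51 (adjusted p = 0.00114, and adjusted p = 0.0541 with an estimated correlation). The list holds the 4 targeted genes, and without them 5 of 13 fell, 2 rose and the median was -0.42 (adjusted p = 0.0454, and adjusted p = 0.114 with an estimated correlation). Trib3, a pseudokinase induced by ATF4 and CHOP, fell from 35.0 ± 6.71 to 3.96 ± 1.70 CPM (-3.14, SE 0.43, adjusted p = 4.09e-06). Ddit4, an inhibitor of mTORC1, fell from 42.9 ± 9.12 to 8.25 ± 0.951 CPM (-2.37, SE 0.32, adjusted p = 3.44e-06). Amino acid synthesis and transport genes fell with them, 11 of 22 against 1 that rose (median -0.59, adjusted p = 0.0043, and adjusted p = 0.363 with an estimated correlation), among them the one-carbon enzyme Mthfd2 (-1.03, SE 0.22) and the glutathione-degrading enzyme Chac1 (-1.49, SE 0.29). Genes of synaptic transmission and excitability were higher: 27 of 34 rose and 2 fell (median 1.04, adjusted p = 2.47e-09, and adjusted p = 0.0713 with an estimated correlation). The calcium channel gene Cacna1a (1.70, SE 0.16), the AMPA receptor gene Gria4 (1.83, SE 0.20) and the potassium channel gene Kcna2 (1.41, SE 0.14) were among these. Amacrine markers moved with them, at 0.578% ± 0.0117 of the reads against 0.196% ± 0.0509 in the controls.

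In the same libraries, 37 of 78 cytosolic ribosomal protein genes rose and 1 fell (41 and 1 adjusted over the list alone, median 0.39, adjusted p = 4.85e-05, and adjusted p = 0.654 with an estimated correlation). Immediate early genes fell, 7 of 15 against 2 that rose (median -0.52, adjusted p = 0.0276, and adjusted p = 0.409 with an estimated correlation), with Ier3 at -1.91, SE 0.22 and the activity-induced factor Npas4 at -2.50, SE 0.44. Cholesterol synthesis genes fell in 6 of 17 cases and rose in 1 (median -0.34, adjusted p = 0.0276, and adjusted p = 0.394 with an estimated correlation), with Msmo1 at -0.76. Innate immune genes fell in 12 of 38 cases and rose in 3 (median -0.14, adjusted p = 0.0493, and adjusted p = 0.642 with an estimated correlation), with the chemokine gene Cxcl10 at -3.30, SE 0.39, while Ccl5 rose (1.53, SE 0.23). Of 26 axon regeneration genes 5 rose and 5 fell, among the latter the endopeptidase gene Ecel1 (-1.55, SE 0.15, adjusted p = 4.11e-08), and the list did not pass (adjusted p = 0.416). Of 13 neuropeptide genes 4 rose with none lower, and that list did not pass either (adjusted p = 0.451). Vip, an amacrine product in the retina, was among them, from 1.25 ± 0.492 to 29.5 ± 13.2 CPM (4.55, SE 0.50). Glycolysis and hypoxia genes fell in 8 and rose in 6 of 24 cases (7 higher adjusted over the list alone) and did not pass (adjusted p = 0.579), with the hexokinase gene Hk2 at -2.42, SE 0.18 and the phosphofructokinase gene Pfkm at 1.18, SE 0.11.

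Cd163l1, a marker of gamma delta T cells, was at 0 in all controls and at 92.8 ± 7.40 CPM in the ATF3 knockouts, at least 1245-fold higher against a floor of 3 reads summed over the control libraries. On the same floor the chemokine receptor gene Ccr8 was at least 135-fold and the interleukin receptor gene Il18r1 at least 94.3-fold higher. The Y-linked Eif2s3y, Ddx3y and Uty fell most, since the controls were male. Other falls were those of Fam160a1 (-4.78), Gramd2 (-4.60) and the water channel gene Aqp1 (-4.59). In all, 5606 of 16797 genes passed the edgeR test, 3125 higher and 2481 lower. Of the 1367 genes called in the authors' deposited table, 1200 were called here in the same direction. Over all genes that both hold, the fold changes correlated at r = 0.507. The immediate early call was lost without control replicate 7 (adjusted p = 0.0521), the cholesterol call without control replicate 4 (adjusted p = 0.0947), and the innate immune call without ATF3 replicate 7 or 8 or control replicate 4 or 7 (adjusted p = 0.0539, 0.0523, 0.0808 and 0.146). The innate immune median was -0.08 without control replicate 7, -0.09 without control replicate 4, -0.21 without control replicate 5, -0.25 without control replicate 8, -0.40 with the library in no group counted as a control and -0.59 with a component of the cell markers as a covariate (adjusted p = 0.074). With the other 2 knockouts of batch 3 as the reference, 1078 genes were called, and 433 of the genes called against control were called there in the same direction (7.72%) and 238 in the opposite direction.

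The knockout of ATF4, the factor at the center of the integrated stress response, comprised 2 libraries. They were compared with the same 4 controls, from which they differ in batch as well. Genes for translation and respiration were higher: 63 of 78 cytosolic ribosomal protein genes rose and 1 fell (68 and 1 adjusted over the list alone, median 0.82, adjusted p = 4.3e-17, and adjusted p = 0.48 with an estimated correlation). In addition, 24 of 30 oxidative phosphorylation genes rose with none lower (median 0.78, adjusted p = 2.3e-10, and adjusted p = 0.398 with an estimated correlation). Examples were Rps3 (1.08, SE 0.16, adjusted p = 1.75e-05), the respiratory chain gene Ndufb9 (1.17, SE 0.15, adjusted p = 4.21e-06) and Cox4i1 (1.14, SE 0.15, adjusted p = 5.56e-06). Synaptic and excitability genes rose in 22 of 34 cases (23 adjusted over the list alone) against 1 that fell (median 0.71, adjusted p = 6.69e-07, and adjusted p = 0.247 with an estimated correlation), led by Cplx2, a regulator of vesicle fusion (2.58, SE 0.20, adjusted p = 6.15e-09). Amacrine markers moved with them, at 0.468% ± 0.0507 of the reads against 0.196% ± 0.0509 in the controls. Innate immune genes fell in 9 of 38 cases with none higher (8 lower adjusted over the list alone, median -0.41, adjusted p = 0.0231, and adjusted p = 0.566 with an estimated correlation), with the interferon response factor Irf1 at -1.83, SE 0.18, adjusted p = 1.34e-07.

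Among stress response regulators in the ATF4 knockouts, 6 of 17 fell and 2 rose, and the list did not pass (median -0.21, adjusted p = 0.524, with medians of -0.03 without ATF4 replicate 3 and -0.39 with the library in no group counted as a control). Trib3 fell (-2.41, SE 0.60), as did the proline synthesis enzyme Aldh18a1 (-1.37, SE 0.28) and the aminoacyl-tRNA synthetases Cars (-1.07, SE 0.17), Lars (-0.98, SE 0.19) and Iars (-1.13, SE 0.25). Of the axon regeneration list, which did not pass (adjusted p = 0.211), 6 of 26 genes rose, among them Basp1 (1.42, SE 0.17) and Stmn4 (1.15, SE 0.17), and 1 fell, Stat3 (-0.94, SE 0.15). Of the apoptosis and p53 list, which did not pass (adjusted p = 0.479), 5 of 22 genes fell, among them Sesn1 (-1.09, SE 0.19), Gadd45a (-1.15, SE 0.20) and Mdm2 (-0.91, SE 0.17), and 1 rose. Neuropeptide genes rose in 6 of 13 cases (adjusted p = 0.0465, and adjusted p = 0.514 with an estimated correlation), with Cartpt at 2.02, SE 0.22. Ganglion cell subtype genes rose in 4 of 23 (adjusted p = 0.0465, and adjusted p = 0.514 with an estimated correlation), with Neurod2 at 2.14, SE 0.26. Müller glia genes rose in 9 of 13 (adjusted p = 0.0229, and adjusted p = 0.566 with an estimated correlation). Il18rap, an interleukin receptor gene, was at 0 in the controls and at least 23.6-fold higher, and Il12rb1 was at 0 in the ATF4 knockouts and at least 31.3-fold lower, on floors of 3 reads summed over the group at 0. In all, 5251 genes passed, 2794 higher and 2457 lower. Of 987 genes called in the authors' deposited table, 866 were called here in the same direction. Over all genes that both hold, the fold changes correlated at r = 0.618. Without ATF4 replicate 1, which leaves 1 library assumed to vary like the other groups, 3358 genes passed and the subtype call was lost (adjusted p = 0.116). The neuropeptide and Müller glia calls were lost without ATF4 replicate 3 (adjusted p = 0.112 and 0.142), the same pair and the subtype call without control replicate 8 (adjusted p = 0.084, 0.0533 and 0.084), and the innate immune call without control replicate 7 (adjusted p = 0.102). The innate immune median was -0.19 without ATF4 replicate 1 and -0.27 without control replicate 7.

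For CEBPG, a bZIP partner of ATF4, 4 knockout libraries were set against the controls. Innate immune genes were higher here, 19 of 38 against 1 that fell (20 and 1 adjusted over the list alone, median 0.62, adjusted p = 0.000281, and adjusted p = 0.299 with an estimated correlation). The median was 0.40 with the library in no group counted as a control. The chemokine gene Ccl5 rose from 13.6 ± 4.36 to 123 ± 33.5 CPM (3.17, SE 0.25, adjusted p = 8.41e-10). The class I histocompatibility genes H2-K1 (1.35, SE 0.12, adjusted p = 2.19e-09) and H2-D1 (1.16, SE 0.13, adjusted p = 1.64e-07) rose too, though these paralogs can share reads. Arg1, the arginase of alternatively activated macrophages, rose from 0.824 ± 0.465 to 91.7 ± 17.9 CPM (6.86, SE 0.69, adjusted p = 3.22e-08). The lymphocyte and microglia shares given above were highest in these libraries. Ribosomal protein genes rose in 62 of 78 cases and fell in 1 (65 and 1 adjusted over the list alone, median 0.85, adjusted p = 6.05e-18, and adjusted p = 0.299 with an estimated correlation). Glycolysis and hypoxia genes fell in 15 of 24 and rose in 4 (5 adjusted over the list alone, median -0.48, adjusted p = 0.000387, and adjusted p = 0.299 with an estimated correlation), with Hk2 at -2.45, SE 0.20 and the pyruvate kinase gene Pkm at -0.95, SE 0.11.

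Stress response regulators in the CEBPG knockouts fell in 5 of 17 cases and rose in 2, and the list did not pass (median -0.34, adjusted p = 0.118, with medians of -0.21 without CEBPG replicate 10, 0.00 without the 4 targeted genes and 0.49 with a component of the cell markers as a covariate). Trib3 (-2.94, SE 0.47), Ddit4 (-1.87, SE 0.34) and the reelin receptor gene Vldlr (-1.36, SE 0.17) fell. Amino acid genes fell in 6 of 22 cases against 1 that rose (median -0.42, adjusted p = 0.0255, and adjusted p = 0.369 with an estimated correlation), with the transporters Slc7a5 at -1.10, SE 0.23 and Slc1a4 at -1.32, SE 0.30. Synaptic genes rose in 17 of 34 cases and fell in 5 (20 and 5 adjusted over the list alone, median 0.57, adjusted p = 0.00373, and adjusted p = 0.369 with an estimated correlation), with Kcna2 at 1.26, SE 0.15. Amacrine markers moved with them, at 0.360% ± 0.0431 of the reads against 0.196% ± 0.0509 in the controls. Of 26 axon regeneration genes 8 rose and 4 fell, among the latter Sprr1a (-3.30, SE 0.86), and of 22 apoptosis and p53 genes 6 rose, among them Casp8 (1.48, SE 0.20), and 2 fell, and neither list passed (adjusted p = 0.481 and 0.303). Gzmk, a granzyme of cytotoxic lymphocytes, was at 0 in the controls and at least 418-fold higher, and Retnlg, a neutrophil gene, at least 431-fold higher. In all, 5608 genes passed, 3082 higher and 2526 lower. Of the 3783 genes called in the authors' deposited table, 3213 were called here in the same direction. Over all genes that both hold, the fold changes correlated at r = 0.828. The amino acid call was lost without CEBPG replicate 6 (adjusted p = 0.0585), without control replicate 4 (adjusted p = 0.0676) and without both CEBPG replicates 6 and 8 (adjusted p = 0.129). Against the other 2 knockouts of batch 3, 4811 genes were called, and 2295 of the genes called against control were called there in the same direction (40.9%) and 426 in the opposite direction.

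CHOP, the product of Ddit3, promotes cell death under prolonged stress, and its 5 knockout libraries were compared with the 4 controls. Stress response regulators fell in 10 of 17 cases and rose in 2 (12 and 2 adjusted over the list alone, median -0.55, adjusted p = 0.000944, and adjusted p = 0.0429 with an estimated correlation). Without the 4 targeted genes 6 of 13 fell (8 adjusted over the list alone), 2 rose and the median was -0.50 (adjusted p = 0.031, and adjusted p = 0.0855 with an estimated correlation). Trib3 fell from 35.0 ± 6.71 to 2.88 ± 1.67 CPM (-3.61, SE 0.44, adjusted p = 6.98e-07) and Ddit4 to 9.32 ± 4.76 CPM (-2.20, SE 0.32, adjusted p = 8.18e-06). Synaptic and excitability genes rose in 27 of 34 cases and fell in 2 (median 1.37, adjusted p = 7.85e-13, and adjusted p = 0.0429 with an estimated correlation), with Cacna1a at 2.14, SE 0.16 and Kcna2 at 1.89, SE 0.14. Amacrine markers moved with them, at 0.727% ± 0.0463 of the reads against 0.196% ± 0.0509 in the controls. Cholesterol synthesis genes were higher, 8 of 17 against 1 that fell (median 0.40, adjusted p = 0.011, and adjusted p = 0.329 with an estimated correlation). Srebf2, the transcription factor that drives this pathway, rose from 106 ± 15.2 to 239.8 ± 9.50 CPM (1.18, SE 0.11, adjusted p = 7.52e-09), with Insig1 (1.16, SE 0.16) and Hmgcs1 (0.81, SE 0.16).

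Innate immune genes in the CHOP knockouts fell in 14 of 38 cases and rose in 3 (median -0.43, adjusted p = 0.00601, and adjusted p = 0.481 with an estimated correlation), with the acute phase factor Cebpd at -1.80, SE 0.20 and Irf1 at -1.07, SE 0.13. Microglia genes took 0.585% ± 0.104 of the reads there and 0.742% ± 0.155 in the controls, with overlap between the libraries. Müller glia genes fell in 6 of 13 cases against 1 that rose (adjusted p = 0.0292, and adjusted p = 0.538 with an estimated correlation). Horizontal cell genes fell in 3 of 6 (adjusted p = 0.0395, and adjusted p = 0.329 with an estimated correlation). Of the apoptosis and p53 list, which did not pass (adjusted p = 0.215), 4 of 22 genes fell, among them Gadd45a (-0.95, SE 0.15), Cdkn1a (-0.89, SE 0.21) and Bcl2l11 (-1.03, SE 0.32), and 1 rose. Of 26 axon regeneration genes 2 rose, among them Basp1 (0.95, SE 0.14), and 4 fell, among them Ecel1 (-1.05, SE 0.15) and Stat3 (-0.66, SE 0.11), and the list did not pass (adjusted p = 0.437). Ccr8 was at 0 in the controls and at least 184-fold higher, and the hedgehog ligand gene Dhh fell (-3.56, SE 0.45). In all, 5625 genes passed, 3036 higher and 2589 lower, and 1152 of the 1249 genes called in the authors' deposited table were called here in the same direction. Over all genes that both hold, the fold changes correlated at r = 0.540. The horizontal cell call was lost without CHOP replicate 5 or control replicate 4 or 7 (adjusted p = 0.0623, 0.0849 and 0.0858), and the Müller glia call without control replicate 4 or 7 (adjusted p = 0.0849 and 0.0824). Against the other 2 knockouts of batch 3, 2413 genes were called, and 1018 of the genes called against control were called there in the same direction (18.1%) and 383 in the opposite direction.

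**Figure D4:**
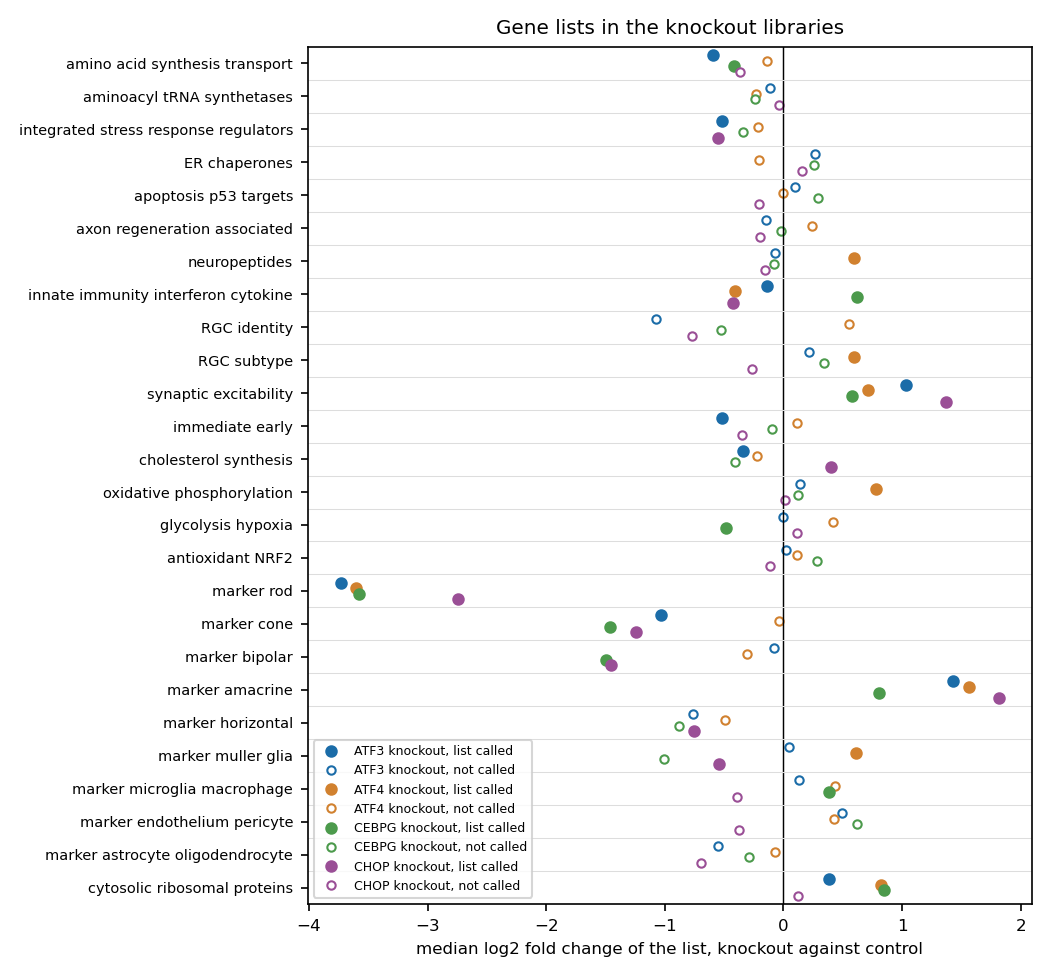
Points are the median log2 fold change of each of the 26 tested gene lists in the ATF3, ATF4, CEBPG and CHOP knockouts against the controls, filled where camera with a preset correlation called the list and open where it did not. Rod markers lie between -3.73 and -2.75, and the innate immune list is at 0.62 in the CEBPG knockouts and below 0 in the other knockouts.

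Across the 4 comparisons, 864 genes were higher and 954 lower in every knockout. Among the 10 highest by mean log2 fold change were Ccr8, Il18rap, Tnfsf11, Cd96, Cd8b1 and Icos, which are expressed in lymphocytes and were at or near 0 in the controls. In the ATF4 knockouts (n = 2) Icos was at 0.694 ± 0.981 CPM and Cd96 at 2.30 ± 3.25 CPM, so these ATF4 calls rest mostly on a single library. The rule for the overlap does not require every library to lie on the same side. The xenobiotic response repressor Ahrr (mean log2 fold change -4.75), the histamine synthesis enzyme Hdc (-4.45), the rod gene Pde6b (-4.29) and the water channel gene Aqp1 (-4.26) were lower in all. The ATF3 and CHOP knockouts shared most, with 2481 genes higher and 1946 lower in both and 12 called in opposite directions, where independent lists would share 564.8 and 382.4. The ATF4 and CEBPG knockouts shared least, with 1196 and 1163 against 512.7 and 369.5, and 316 in opposite directions. Groups simulated without change against the same controls shared 0 calls in all 20 simulations, which follows from the lack of changes put in and tests no sharing. The comparisons share their controls, so their lists are not independent. With the controls split between the knockouts, in 6 ways, 512.8 genes were higher and 692.8 lower in all 4 on average. ATF3 and CHOP then shared 1528.7 higher and 1249.7 lower, and ATF4 and CEBPG 777.8 and 894.5, with fewer controls in each comparison. The fold changes correlated across genes at a mean r of 0.602, against 0.508 in the simulation and 0.372 with split controls. For ATF4 and CEBPG the r of 0.383 lay below the simulated 0.413. Genes are not independent replicates. The covariance of the fold changes was 1.17 to 1.96, against 0.375 to 0.399 simulated. All 4 knockouts differ from the controls in batch as well, so batch enters every shared value.

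Comparing the ATF3 with the CHOP knockouts, 5 libraries each from the same batch and sex, tests where they differ without the controls. Cholesterol synthesis genes were lower in the ATF3 knockouts, 13 of 17 with none higher (median -0.82, adjusted p = 3.62e-24, and adjusted p = 0.00029 with an estimated correlation). Bipolar cell genes were higher in the ATF3 knockouts, 10 of 12 with 1 lower (median 1.31, adjusted p = 1.72e-15, and adjusted p = 0.0124 with an estimated correlation). Rod genes were lower in 9 of 14 (13 adjusted over the list alone, adjusted p = 7.94e-16, and adjusted p = 0.0945 with an estimated correlation). Microglia genes were higher in 4 of 15 cases (12 adjusted over the list alone, adjusted p = 1.76e-09, and adjusted p = 0.192 with an estimated correlation). Müller glia genes took 1.29% ± 0.0642 of the reads in the ATF3 and 0.723% ± 0.0646 in the CHOP knockouts, and amacrine genes 0.578% ± 0.0117 and 0.727% ± 0.0463, with no overlap between the libraries of the groups. Saa3, an acute phase serum amyloid, was at 449 ± 38.2 CPM in the ATF3 and 5.16 ± 3.39 CPM in the CHOP knockouts (log2 difference 6.40, SE 0.38, adjusted p = 2.02e-10). Lcn2, an iron-binding protein of inflammation, was higher by 3.64, SE 0.35, adjusted p = 1.48e-06. Eps8l1 (-2.90, SE 0.35) and the macrophage metalloelastase Mmp12 (-2.05, SE 0.35) were lower. In all, 380 genes passed, 253 higher in the ATF3 and 127 higher in the CHOP knockouts. DESeq2 called 678, and without CHOP replicate 4 or ATF3 replicate 9 the edgeR count was 232 or 245.

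The CEBPG knockouts were compared with the ATF3 and CHOP knockouts within the same batch. Innate immune genes were higher in the CEBPG knockouts, 26 of 38 with none lower against CHOP (median 1.07, adjusted p = 4.73e-14, and adjusted p = 0.0443 with an estimated correlation). Against ATF3 the counts were 24 higher and 1 lower (adjusted p = 9.75e-13, and adjusted p = 0.0925 with an estimated correlation). Arg1 was at 91.7 ± 17.9 CPM in the CEBPG and 1.80 ± 1.17 CPM in the CHOP knockouts (5.72, SE 0.56, adjusted p = 1.03e-07). Lymphocyte genes moved with the innate immune genes, at 0.358% ± 0.0556 of the reads in the CEBPG, 0.0607% ± 0.00316 in the ATF3 and 0.0680% ± 0.0123 in the CHOP knockouts, as did microglia genes, at 1.15% ± 0.0569, 0.768% ± 0.0355 and 0.585% ± 0.104. Dusp2, a phosphatase of activated lymphocytes, was at 283 ± 22.5 CPM in the CEBPG and 16.9 ± 1.92 CPM in the ATF3 knockouts (-4.06, SE 0.25, adjusted p = 5.66e-10, ATF3 minus CEBPG). The interferon gamma gene Ifng differed by -4.60, SE 0.79, adjusted p = 0.000189 in the same sense. Ribosomal protein genes were also higher, 66 of 78 against CHOP (median 0.71, adjusted p = 4.17e-27, and adjusted p = 0.12 with an estimated correlation). Genes of p53 and apoptosis were higher in 8 of 22 (adjusted p = 0.00273, and adjusted p = 0.0835 with an estimated correlation). Against CHOP, synaptic genes were lower in 25 of 34 cases (adjusted p = 1.22e-10, and adjusted p = 0.0663 with an estimated correlation), and amacrine markers were lower too, at 0.360% ± 0.0431 against 0.727% ± 0.0463 of the reads. Glycolysis genes were lower in 17 of 24 (adjusted p = 7.17e-08, and adjusted p = 0.0835 with an estimated correlation) and cholesterol synthesis genes in 12 of 17 (median -0.82, adjusted p = 7.17e-08, and adjusted p = 0.0443 with an estimated correlation). Stress response regulators were higher in CEBPG than in the mean of the other pair, 6 of 17 with 2 lower (median 0.42, adjusted p = 0.0289, and adjusted p = 0.123 with an estimated correlation). Without the 4 targeted genes that call was lost (median 0.43, adjusted p = 0.129). In all, 3419 genes differed between ATF3 and CEBPG, 1701 higher in ATF3 and 1718 higher in CEBPG, and 4478 between CEBPG and CHOP, 2264 higher in CEBPG and 2214 higher in CHOP.

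**Figure D5:**
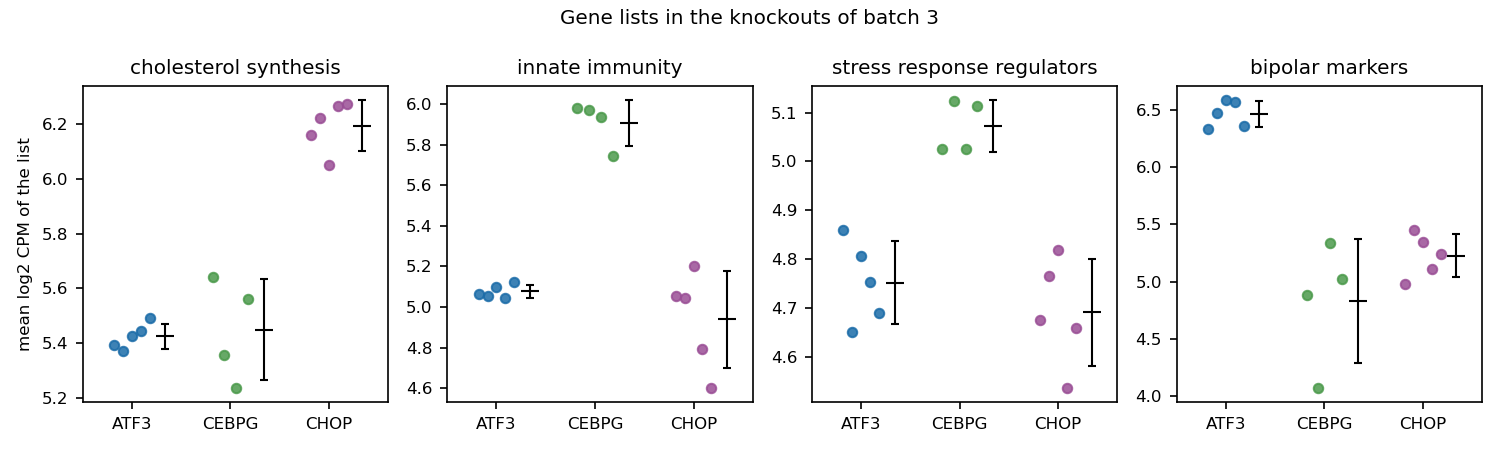
Points are the mean log2 CPM of 4 gene lists in each ATF3 (n = 5), CEBPG (n = 4) and CHOP (n = 5) knockout library, with the group mean ± SD beside them. The CHOP libraries lie above all others in cholesterol synthesis genes, the CEBPG libraries above all others in innate immune genes and stress response regulators.

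Counting the genes called against the controls and against both other knockouts of batch 3 in 1 direction left 59 for ATF3 (40 higher, 19 lower), 1500 for CEBPG (1003 higher, 497 lower) and 105 for CHOP (45 higher, 60 lower).

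The ATF4 knockouts differ from the other knockouts in batch as well. Oxidative phosphorylation genes were higher in ATF4 than in ATF3 (25 of 30, adjusted p = 5.51e-11, and adjusted p = 0.324 with an estimated correlation), CEBPG (26, adjusted p = 1.15e-09, and adjusted p = 0.208 with an estimated correlation) and CHOP (25, adjusted p = 1.09e-14, and adjusted p = 0.214 with an estimated correlation). Cone genes were higher in ATF4 as well, 6 of 10 against ATF3 (adjusted p = 0.000557, and adjusted p = 0.287 with an estimated correlation), 7 against CEBPG (adjusted p = 1.66e-05, and adjusted p = 0.155 with an estimated correlation) and 7 against CHOP (adjusted p = 2.59e-05, and adjusted p = 0.211 with an estimated correlation). The inhibitor of differentiation Id1 was at 31.3 ± 0.418 CPM in the ATF4 and 3.42 ± 0.867 CPM in the ATF3 knockouts (-3.19, SE 0.55, adjusted p = 0.000268, ATF3 minus ATF4). Cd163l1 was at 0 in the ATF4 knockouts and at least 738-fold higher in the ATF3 knockouts. The Y-linked Eif2s3y, Ddx3y and Uty had reads in the ATF4 libraries and none in the others, while Tsix and Xist had far more reads in the others. These last overlap on opposite strands and cannot be told apart where strand is not stated. In all, 4144 genes differed between ATF3 and ATF4 (2168 higher in ATF3), 5197 between ATF4 and CEBPG (2582 higher in ATF4) and 4317 between ATF4 and CHOP (2098 higher in ATF4). Without ATF4 replicate 1 these counts were 1596, 3234 and 1739.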

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

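The tests of rod counts lifting other genes, of sex for the rod fall, of batch or sex for the stress response, of that list without the targeted genes, and of the lymphocyte list were chosen or written only after part of the result was seen.

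Of 128 groups of values tested for a library far from the others of its group, 5 held one, where chance gives about 1 in 20. Control replicate 5 had 6401446 counted reads, and the other controls 11395201 to 11752828 (gap over range 0.933). ATF3 replicate 5 had the lowest mean log2 CPM of tRNA synthetase genes of its group, 6.70 with the nearest at 6.79 (0.782), and the highest of oxidative phosphorylation genes, 7.52 with the nearest at 7.39 (0.796). ATF3 replicate 6 was lowest in glycolysis genes, 7.96 with the nearest at 8.08 (0.744). CHOP replicate 3 was lowest in tRNA synthetase genes, 6.69 with the nearest at 6.84 (0.727). The library in no group held Atf3 at 225.2 CPM, above the highest control at 125.2 CPM.

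Rod genes were lower and amacrine genes higher in all knockout groups. Loss of the reads of the listed rod genes alone lifts every other gene by 0.0726 on the log2 scale, while the smallest amacrine median was 0.81. Other transcripts of rods are not in that value, so it cannot decide whether loss of rod reads lifted the amacrine genes. Sex is excluded as the source of the rod fall in the ATF4 libraries, which carry Y-linked reads as the controls do. Their rod median was still -3.60. The ATF3, CEBPG and CHOP knockouts were all female and no male library shared their batch, so sex stays open for their rod fall. Rod genes deviated together within groups, with a mean pairwise correlation of 0.738 against 0.0868 at a high percentile of 1000 random lists, so different amounts of rod cells carried through the sort are a candidate source. A batch difference in that carry-over and an effect of the knockouts remain open, because each knockout differs from the controls in batch.

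Stress response regulators were lower in the ATF3 and CHOP knockouts than in the controls. The choice of TMM over DESeq2 size factors or upper-quartile factors is excluded as the source, with medians of -0.49 or lower under these. An error that all these library-wide scalings share was not tested. Depth is excluded as well, with medians of -0.52 or lower once every library was thinned to the shallowest. Without the 4 targeted genes, which the list holds, these medians were -0.39 or lower and -0.43 or lower. The CEBPG libraries, of the same batch and sex, lay above the ATF3 and CHOP libraries by 0.35 in the mean log2 CPM of the list. The exact two-sided permutation p = 0.000999 was the smallest that 1001 splits can give. Without the targeted genes the difference was 0.32 (the same p, with camera at adjusted p = 0.129). Batch or sex cannot give this difference between knockouts, and leukocyte content stays open for it. It does not show whether CEBPG was raised or ATF3 and CHOP were lowered, so it accounts for no part of the fall against the controls. That fall cannot be told apart from batch and sex, and loss of ATF3 or CHOP and a different cell content stay open for it. Markers of other cells moved with the groups. The marker component as a covariate, 98.0% of which lies between groups, cannot separate cell content from knockout (medians of -0.18 and -0.05, adjusted p = 0.668 and 0.434).

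Immune genes were higher in the CEBPG knockouts than in the ATF3 and CHOP knockouts. The 28 genes of the lymphocyte list, none of which another list holds, had a median difference of 2.40 and 26 were called higher, so leukocytes carried into these libraries are a candidate source. Its most abundant genes were Cxcr6 at 596 ± 121 CPM in the CEBPG, 121 ± 14.6 CPM in the ATF3 and 1.56 ± 0.722 CPM in the control libraries, and Lck at 426 ± 83.7, 54.2 ± 6.87 and 2.88 ± 0.336 CPM, and a sort of ganglion cells would be meant to remove such cells. CEBPG replicates 6 and 8, which stand apart, are not the source, since without them the innate immune median was 1.02 (1.02 with them). Whether loss of CEBPG in the neurons draws such cells in was not tested.

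Other splits of the same libraries gave fewer called genes than the real groups. Only the real split called as many, 1 of 100 splits drawn, or 1 of 35 for CEBPG against control. This argues against a random division of independent libraries as the source of these counts. Libraries of a group that shared an animal could give the same outcome, and the labels do not say whether they did. ATF3 against control called 5606 with 2598 as the highest of the others, CEBPG against control 5608 with 596, CHOP against control 5625 with 3431, ATF3 against CEBPG 3419 with 1281, ATF3 against CHOP 380 with 0 and CEBPG against CHOP 4478 with 2567. Except for CEBPG against control and ATF3 against CHOP, the highest other split exchanged 4 libraries and so nearly exchanged the names of the groups. Against the controls the real split is also the split by batch, which this count does not separate.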

How the results depend on the processing

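Fits against the other knockouts of the batch, at equal depth, without X and Y genes, without rod and cone genes, without CEBPG replicates 6 and 8 and with the stress response list without the targeted genes were chosen after the data were seen. Of 605 values of named genes, 602 kept direction and call with DESeq2 size factors and 601 with DESeq2, and of 4868 values with a library left out 4617 did, 249 lost the call, 2 gained it and 0 reversed. Of 39 list calls against control, 39 were kept under DESeq2 size factors and under fry, 3 with an estimated correlation, and 9 with the marker component, where 22 lost the call and 8 reversed. Without the targeted genes the stress response list, which is 2 of the 39, kept its calls for ATF3 and CHOP and lost that for CEBPG against the other knockouts of the batch (adjusted p = 0.129). With the marker component its medians were -0.18, -0.02, 0.49 and -0.05 for ATF3, ATF4, CEBPG and CHOP.

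With the first component of the cell markers as a covariate, calls against control fell to 4 for ATF3, 2 for ATF4, 18 for CEBPG and 17 for CHOP, to 147 for ATF3 against CHOP and to 2102 for CEBPG against CHOP, and 2 lists were called for ATF4. This follows from its construction, since 98.0% of that component lies between groups. Under it these lists turned with no call: immediate early genes for ATF3 (adjusted p = 0.492), neuropeptides, ganglion cell subtype and Müller glia for ATF4 (0.314, 0.828 and 0.0855), synaptic, rod and amacrine genes for CEBPG (0.294, 0.648 and 0.417) and rod genes for CHOP (0.518). The sequencing quality covariate, 72.6% of which lies between groups, left 2142 calls for ATF3 and 3316 for CHOP. Requiring a log2 fold change of at least 1 left 2625, 2973, 3054 and 2783 calls for ATF3, ATF4, CEBPG and CHOP by construction. Against the other knockouts of batch 3, ATF3 had 1078 calls and CHOP 2413. DESeq2 called 678 for ATF3 against CHOP, and the cause was not tested. With an estimated correlation 0, 0, 0 and 3 lists were called for ATF3, ATF4, CEBPG and CHOP, and with fry, which tests movement in a direction and not against other genes, 16, 15, 21 and 16. Split controls gave 1205.67 genes shared by all 4 and a mean r of 0.372.

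Leaving out each library gave 3358 to 5592 calls for ATF4 against control, 1596 to 3862 for ATF3 against ATF4, 3234 to 5186 for ATF4 against CEBPG and 1739 to 4330 for ATF4 against CHOP, each lowest without ATF4 replicate 1, and 232 to 353 for ATF3 against CHOP, lowest without CHOP replicate 4 and next 245 without ATF3 replicate 9. Without 1 library the targeted Cebpg lost its call in ATF3 (adjusted p up to 0.097) and ATF4 (0.229 without replicate 3), and Ddit3 in CEBPG (0.0874 without control replicate 7).

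Replicate numbers did not pair the libraries, as the deviations of libraries of the same number in 2 groups correlated at r from -0.33 to 0.28 over 10 pairs. The replicate block over shared numbers left 2967 calls for CHOP against control, 2220 for ATF3 against CEBPG and 2267 for ATF4 against CHOP, with fewer libraries in the fit, and 4117 for ATF3 against control. No paired analysis was possible for ATF4 or CEBPG against control because they share fewer than 2 numbers. A batch covariate could not be fitted, because batch follows the groups, and was not run.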

Other observations

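Ganglion cell identity genes moved both ways, and their list passed in no comparison with the controls. Thy1, a surface protein of ganglion cells and, in mice, of T cells, rose in the ATF4 (2.17, SE 0.33), CEBPG (1.96, SE 0.29) and CHOP (1.56, SE 0.28) knockouts, and the transcription factor gene Ebf3 rose in all 4, most in CHOP (3.06, SE 0.36). Jam2, a cell adhesion gene of a ganglion cell subtype, fell in the ATF3 (-1.86, SE 0.17), ATF4 (-2.27, SE 0.25), CEBPG (-2.04, SE 0.19) and CHOP (-2.14, SE 0.17) knockouts, and Sncg fell in the ATF3 (-1.35, SE 0.22) and CHOP (-1.98, SE 0.23) knockouts. Among antioxidant genes, whose list did not pass against control either, the heme oxygenase gene Hmox1 rose in the ATF3 (1.19, SE 0.18) and CEBPG (2.13, SE 0.19) knockouts, the metallothionein gene Mt1 in ATF4 (1.49, SE 0.18), and the malic enzyme gene Me1 fell in CEBPG (-1.44, SE 0.20) and CHOP (-0.92, SE 0.18).

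The monocyte and neutrophil list, written after immune genes were seen, had 11 of 17 measured genes higher and 1 lower in CEBPG than in the other 2 knockouts of batch 3 (camera, adjusted p = 0.000255, and adjusted p = 0.0939 with an estimated correlation), and 13 lower and 0 higher in CHOP (adjusted p = 7.45e-10, and adjusted p = 0.0107 with an estimated correlation). Some of its genes had no reads in the CHOP libraries. Its genes took 0.0357% ± 0.00560 of the reads in the controls, 0.0819% ± 0.00225 in the ATF3, 0.0424% ± 0.000955 in the ATF4, 0.0976% ± 0.00741 in the CEBPG and 0.0559% ± 0.00752 in the CHOP knockouts. Of the 28 lymphocyte genes, 27 were called higher than in the controls in ATF3, 27 in CEBPG, 25 in CHOP and 14 in ATF4, where 1 was called lower.

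The library with a control title and a CHOP genotype came from a male mouse and batch 4. Ddit3 was at 50.5 CPM in it, below the controls (75.2 to 108.9 CPM) and the CHOP knockouts (57.3 to 72.5 CPM). Trib3 was at 13.9 CPM, between the CHOP knockouts (0.631 to 5.03 CPM) and the controls (30.4 to 44.8 CPM). The mean log2 CPM of the stress response regulators was 5.66, above the controls (5.49 to 5.59) and the CHOP knockouts (4.53 to 4.82). Rod genes took 0.825% of its reads, below the controls (3.99% to 6.04%) and within the CHOP knockouts (0.547% to 0.927%), cone genes 1.35%, and T and NK lymphocyte genes 0.00153%, against a mean of 0.00305% in the controls and 0.0680% in the CHOP knockouts. Its log2 CPM correlated across genes with the controls at a mean of 0.908, with the ATF3 knockouts at 0.903, ATF4 at 0.882, CHOP at 0.873 and CEBPG at 0.844, and genes are not independent replicates.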
